A study of Rattus norvegicus with 24 samples.

How the data were processed

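RNA-seq libraries of the rat cell line PC6.3 were analysed, 4 from untreated cells (Day0) and 4 from each of 5 days of treatment with 50 ng/ml NGF (Day1 to Day5). The group and the replicate number of each library were taken from its title in the labels, and the series' design text calls the replicates biological. Per the labels' protocols, cells were grown in medium with horse and bovine serum, and for differentiation they were plated on coated plates and moved to low serum with NGF. RNA came from a Nucleospin kit, its polyadenylated part was sequenced, and libraries were made with the NEBNext Ultra Directional kit, which keeps the strand of the RNA.

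The authors deposited a table for each library with the raw read count of every Ensembl gene and the gene's position. Per the submitters' processing notes the tools were TopHat2, HTSeq and DESeq and the genome build was Rnor_6.0. Their versions, roles and settings, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes and of near-identical copies may therefore have been divided or dropped in ways the counts do not show. The deposited counts were whole numbers with a different total in each library, between 17494172 and 56066369. Start positions count from 0 in the files (the first mitochondrial gene starts at 0) and are printed from 1. The files hold 32883 genes, of which 37 are mitochondrial. Every entry was a gene, so reads outside genes were not listed.

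The files do not pair gene identifiers with names. The reference gene table used here belongs to the assembly GRCr8, and 0 of the identifiers matched it. The gene lists fixed before the data were examined (such as MRTF/SRF targets, actin regulators, neuronal and cell cycle genes) are lists of names and were not tested, apart from the genes encoded by the mitochondrial genome, which are given by the chromosome column. In their place, groups that the files define were tested: chromosomes, and classes of genomic span. These groups and the analysis of neighbouring genes were chosen after the files were seen. The rule fixed beforehand for the genes the text names took those with the largest rise and the largest fall on Day1 and on Day5 against Day0, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in either group and no overlap between the libraries of the 2 groups. It also asked for a gene name, took more genes per direction, took genes for the later steps and the gene lists, and always included a fixed set of genes by name. Without names it was reduced to 1 rise and 1 fall for each of Day1 and Day5, passing over genes already taken.

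Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 6 groups, which kept 13549. Libraries were scaled with TMM, and CPM values use the TMM-scaled library sizes. A quasi-likelihood model with a mean for each day was fitted to all 24 libraries, which share the estimate of spread with 18 residual degrees of freedom. The 10 contrasts were two-sided (each treated day against Day0, each day against the day before, and Day5 against Day1), and an F-test asked for any difference among the 6 days. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. A change of at least 2-fold means an absolute log2 fold change of at least 1. A fold against a group with 0 reads is a lower bound, with that group set to 3 reads over its libraries. Gene groups with at least 3 tested members were compared with camera in limma 3.58.1. Adjacent tested genes were counted against 1000 shuffles of the gene order within chromosomes, which ignore the local density and levels of genes.

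The tests were checked on simulated counts for Day1 against Day0 with the real means and library sizes, over 13392 genes. Of the genes changed 1.5-fold, 52.2% were recovered, of those changed 2-fold 76.1%, and of those changed 4-fold 87.9%, with 6 false calls. Simulated unchanged libraries of Day5 against Day4 gave 1 call. The simulated libraries were drawn independently around the mean over all days, without the difference of replicate 4 described below, so these rates do not cover it. No libraries of a group were duplicates: the lowest chi-square per degree of freedom between 2 libraries of a group was 5.18, where sampling noise alone gives about 1.

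The alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors in place of TMM, no filter on low counts, a stricter filter of 5 CPM in 4 libraries, DESeq2 1.42.0 and limma-voom in place of edgeR, only the 2 groups compared in the fit, the replicate number as a block, and leaving out each library in turn. A pair of alternatives was added after replicate 4 was seen to stand apart: replicates 1 to 3 only, and replicate 4 as a batch term. Every other split of the 8 libraries of a comparison into groups of 4 was also tested, in a fit of those libraries alone.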

Results

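Polyadenylated RNA was sequenced from PC6.3 cells, a neuron-like rat line of pheochromocytoma origin that stops dividing and grows neurites when given nerve growth factor (NGF). The series follows these cells as they differentiate, and its title asks about nuclear actin and the target genes of the MRTF/SRF transcription factors. The files list genes by Ensembl identifier and do not pair the identifiers with names, so the actin, MRTF/SRF and neuronal genes are not singled out here, and genes are described by identifier, by position on the Rnor_6.0 rat genome or by group. Untreated cells (Day0) and cells kept for 1, 2, 3, 4 or 5 days in 50 ng/ml NGF (Day1 to Day5) were sampled in 4 biological replicates each, which gave 24 libraries. The NGF medium also had less serum, and the plates for differentiation were coated with poly-L-lysine and laminin. No library of untreated cells in low serum is among the samples, so every comparison with Day0 covers NGF, serum and coating together. Counts assigned to genes summed to between 17494172 and 56066369 per library. Of 32883 annotated genes, 12424 had no count in any library and 13549 were tested. At this depth, 3 reads over the 4 Day0 libraries correspond to 0.0273 CPM (counts scaled to library size), and this floor covers counting error only.

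The day of treatment gave the main order of the libraries. The first principal component, with 42.2% of the variance, ran from a mean of -60.2 ± 10.1 (SD, n = 4) on Day0 to -26.2 ± 15.7 on Day1, -4.61 ± 9.56 on Day2, 22.2 ± 3.19 on Day3, 33.6 ± 3.69 on Day4 and 35.4 ± 11.4 on Day5. Replicate 4 stood apart from replicates 1 to 3 on all 6 days. On PC3, with 11.7% of the variance, replicate 4 lay below the range of the other three replicates on each day, for example at -13.4 against 19.4 to 23.9 on Day0 and at -28.6 against 16.6 to 19.6 on Day5. With the day in the model, 4925 genes differed between replicate 4 and the others by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels give no date or batch for any library. Counts of genes from replicates 1 to 3 alone are therefore given beside those from all 4 replicates.

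**Figure D1:**
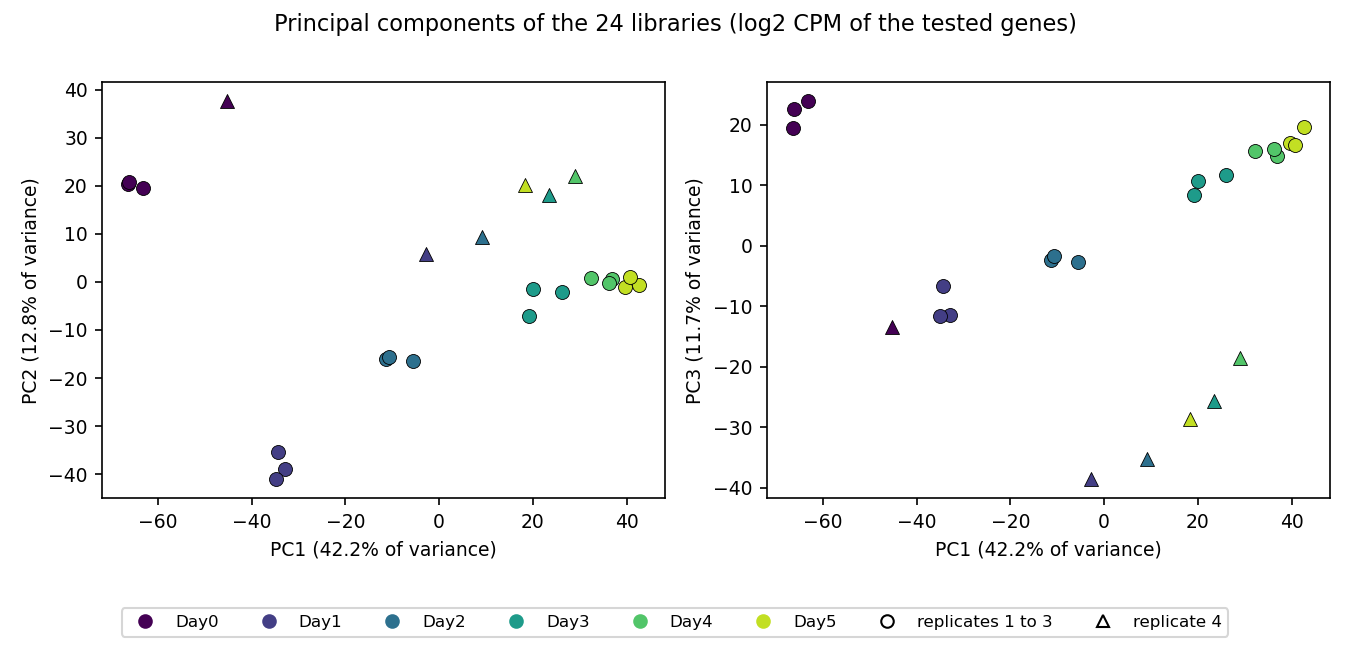
Principal components of the 24 libraries, from log2 CPM of the tested genes, with PC1 (42.2% of the variance) on both horizontal axes and PC2 (12.8%) or PC3 (11.7%) on the vertical axes. Each point is a library, coloured by day, with replicate 4 as triangles: the means of the days follow one another along PC1, with the Day5 library of replicate 4 (18.3) below the Day3 libraries (19.2 to 26.1), and the replicate 4 libraries lie below the other libraries of their day on PC3.

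After 1 day of treatment 2321 genes were higher and 1963 lower than on Day0, together 31.6% of the genes tested. Among them 538 were at least 2-fold higher and 313 at least 2-fold lower (336 and 180 with a filter of 5 CPM in 4 libraries, which tests fewer genes). Of the genes that had at most 3 reads over the 4 Day0 libraries, 11 were called and reached a mean of 1 CPM on Day1, and none that was at 1 CPM or more on Day0 dropped to 3 reads or fewer. The genes were called with edgeR's quasi-likelihood test at an adjusted p under 0.05, with Benjamini-Hochberg adjustment. Replicates 1 to 3 alone gave 2894 genes higher and 2680 lower, and 4135 of the 4284 genes called with all libraries were called in the same direction there.

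The number of genes that differed from Day0 was larger from Day3 on. On Day2, 2243 genes were higher and 1896 lower than on Day0. The counts were 3000 and 2721 on Day3, 3195 and 2985 on Day4, and 3202 and 2926 on Day5. Rises of at least 2-fold outnumbered falls of that size on every treated day and made up 63.2% of such changes on Day1, 75.3% on Day2, 78.5% on Day3, 75.1% on Day4 and 73.5% on Day5, when 1232 genes were at least 2-fold higher and 444 at least 2-fold lower. With a filter of 5 CPM in 4 libraries, which tests fewer genes, 564 and 253 were on Day5. Genes with at most 3 reads on Day0 that were called and reached 1 CPM numbered 12 on Day2, 17 on Day3, 25 on Day4 and 33 on Day5, and 7 of those on Day5 reached 5 CPM. In the opposite direction, 1 gene at 1 CPM or more on Day0 was down to 3 reads or fewer on Day5. Replicates 1 to 3 alone gave 3811 genes higher and 3597 lower on Day5. There, 57 called genes with at most 3 reads over their 3 Day0 libraries reached a mean of 1 CPM. That limit is looser than 3 reads over 4 libraries, so the 57 and the 33 were not counted alike. In a test of any difference among the 6 days, 7552 genes were called, which is 55.7% of those tested.

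**Figure D2:**
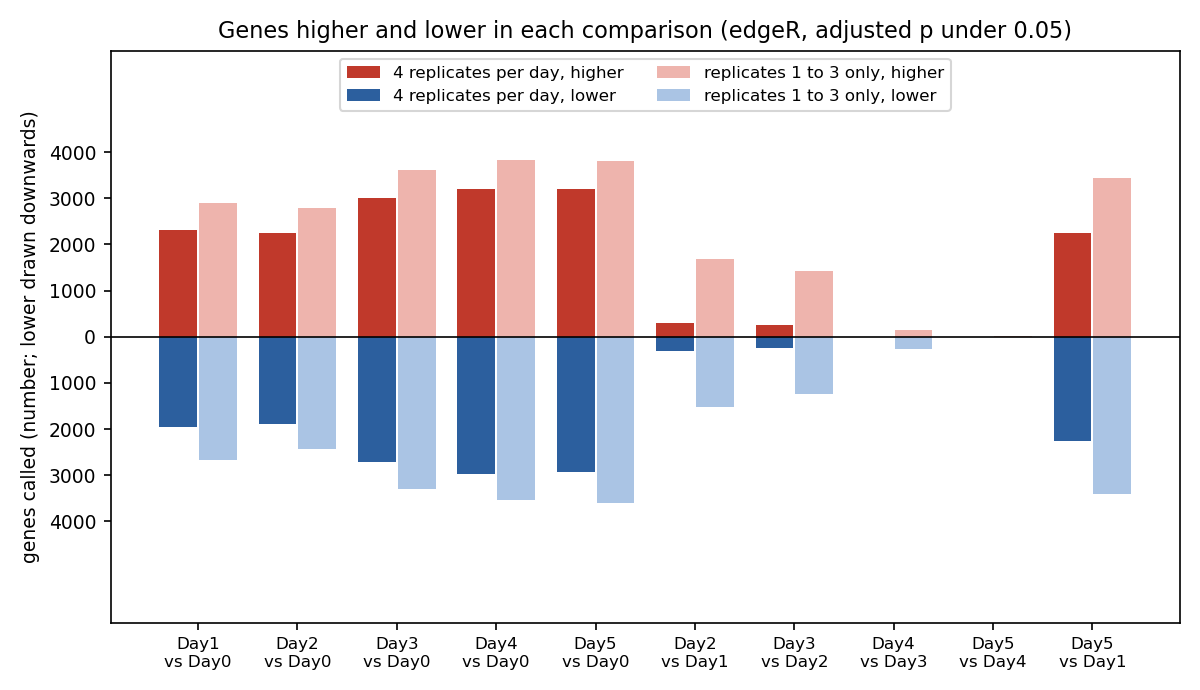
Number of genes higher (drawn upwards) and lower (drawn downwards) in each of the 10 comparisons at an edgeR adjusted p under 0.05, with dark bars for all 4 replicates per day and pale bars for replicates 1 to 3 only. Calls against Day0 went from 2321 higher and 1963 lower on Day1 to 3202 and 2926 on Day5, calls between successive days with the same libraries went from 302 and 306 for Day2 against Day1 to 256 and 234 for Day3 against Day2, and 0 genes were called between Day4 and Day5 with all 4 replicates.

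The largest rise on Day1, among genes at 5 CPM or more whose 4 Day1 libraries all lay above the 4 Day0 libraries, was that of ENSRNOG00000049882, on the minus strand of chromosome 9 from 121706979 to 121725716. It had 0 reads in the Day0 libraries and 16.2 ± 8.76 CPM (SD, n = 4) on Day1, at least 595-fold higher when Day0 is set to 3 reads over its libraries (edgeR adjusted p = 5.86e-06). It reached 75.1 ± 32.4 CPM on Day4 and 65.2 ± 36.2 CPM on Day5, at least 2390-fold above Day0. Its level was lower in replicate 4 than in the other three replicates on each treated day, with 12.2 CPM against 82.8 ± 9.82 CPM (SD, n = 3) on Day5. With limma-voom the Day1 rise had an adjusted p of 0.051, and over all 18 alternatives that p ranged from 5.51e-19 to 0.051.

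The largest rise on Day5 not already named was that of ENSRNOG00000029342, on the minus strand of chromosome 3 from 52777214 to 52849907. It also had 0 reads on Day0, then 4.28 ± 2.01 CPM (SD, n = 4) on Day1, at least 157-fold higher than Day0 (edgeR adjusted p = 1.74e-06), and 10.2 ± 4.45 CPM on Day5, at least 374-fold higher (adjusted p = 1.04e-07). Here replicate 4 was the highest library on Day5, at 16.4 CPM against 8.13 ± 1.99 CPM (SD, n = 3) in replicates 1 to 3.

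The largest falls by the same rule, on Day1 and on Day5, were both on chromosome X. ENSRNOG00000002487, on the minus strand from 138384912 to 138435391, fell from 18.2 ± 5.16 CPM (SD, n = 4) on Day0 to 2.53 ± 1.46 CPM on Day1, with a log2 fold change of -2.84 (SE 0.37, edgeR adjusted p = 2.07e-06). It stayed near that level, at 2.53 ± 1.43 CPM on Day5. ENSRNOG00000003587, on the minus strand from 31816436 to 31851715, fell in 2 steps on average. It was at 34.4 ± 15 CPM on Day0, 6.26 ± 4.18 CPM on Day1 and 1.53 ± 0.754 CPM on Day2, and its step from Day1 to Day2 passed the test (log2 fold change -2.01, SE 0.55, edgeR adjusted p = 0.0363). On Day5 it was 21.7-fold below Day0 (log2 fold change -4.44, SE 0.57, adjusted p = 1.31e-06). Replicate 4 began lower, at 12 CPM on Day0 against 41.9 ± 0.306 CPM (SD, n = 3), and had no second step: it was at 0.366 CPM on Day1 and 0.673 CPM on Day2, against 8.23 ± 1.74 CPM and 1.82 ± 0.601 CPM in the others. None of these 4 genes overlaps another annotated gene.

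**Figure D3:**
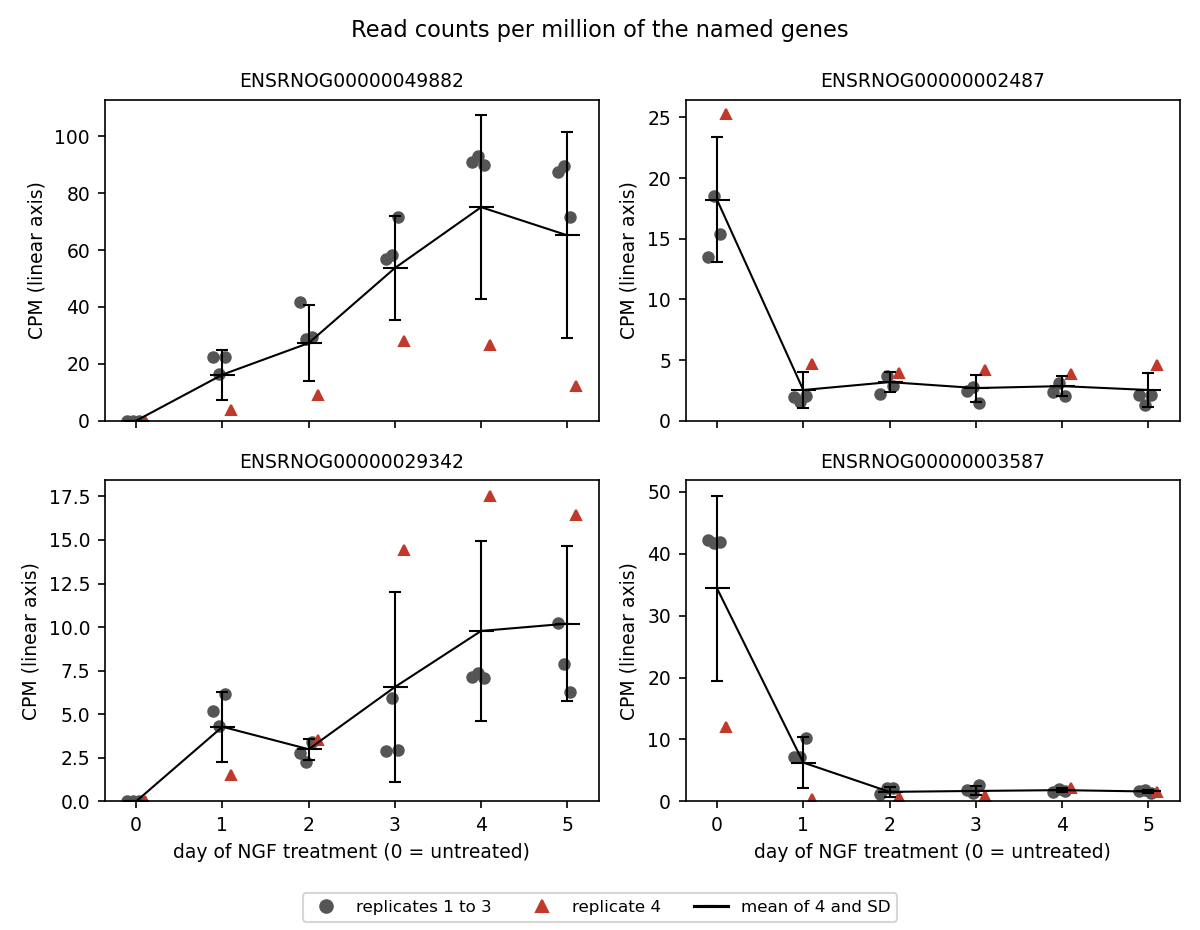
CPM on a linear axis, against the day of NGF treatment, of the 2 genes with the largest rises (left) and the 2 with the largest falls (right), with a point per library, replicate 4 as triangles, and the mean and SD of the 4 libraries in black. Both rising genes start from 0 reads on Day0, and ENSRNOG00000002487 fell to 2.53 CPM by Day1 while the mean of ENSRNOG00000003587 went to 6.26 CPM on Day1 and 1.53 CPM on Day2, with replicate 4 already at 0.366 CPM on Day1.

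Fewer genes were called between successive days than against Day0. From Day1 to Day2, 302 genes rose and 306 fell, and from Day2 to Day3, 256 rose and 234 fell. Replicates 1 to 3 alone gave 1689 genes higher and 1515 lower on Day2 than on Day1, and 1430 higher and 1246 lower on Day3 than on Day2. With the Day1 and Day2 libraries alone in the fit, 7 genes were higher and 1 was lower, and with those of Day2 and Day3 alone, 144 and 91. Of the 608 genes called from Day1 to Day2 and the 490 from Day2 to Day3, replicates 1 to 3 alone called 606 and 489 in the same direction. The counts of both steps moved when single libraries were left out. From Day1 to Day2, leaving out Day1 replicate 1, 2 or 3 gave 89, 93 or 115 genes higher and 84, 79 or 128 lower, and leaving out Day1 replicate 4 gave 1334 higher and 1143 lower. Leaving out Day2 replicate 1, 2 or 3 gave 160, 120 or 137 higher and 227, 133 or 137 lower, and leaving out Day2 replicate 4 gave 319 and 243. From Day2 to Day3, leaving out Day2 replicate 2 or 3 gave 54 or 68 higher and 62 or 79 lower. Without Day2 replicate 1 the counts were 300 and 234, and without Day2 replicate 4 they were 475 and 456. Leaving out Day3 replicate 1, 2 or 3 gave 141, 103 or 117 higher and 119, 111 or 115 lower, and leaving out Day3 replicate 4 gave 257 and 202.

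From Day3 to Day4, edgeR called 0 genes higher and 1 lower. An unadjusted p under 0.05, which a share of 0.05 of unchanged genes would reach by chance, was found for 789 of the 13549 genes tested. DESeq2 called 0 higher and 3 lower, limma-voom called 0 in either direction, and edgeR with replicate 4 as a batch term called 7 higher and 5 lower. The gene that fell lies on the plus strand of chromosome 8 from 73593310 to 73594332 and is described here because it was the only call, after its values were seen. It was at 7.57 CPM on Day0, 1.76 ± 0.795 CPM (SD, n = 4) on Day3 and 0.327 ± 0.114 CPM on Day4 (log2 fold change -2.41, SE 0.38, edgeR adjusted p = 0.0191). Without Day3 replicate 1 or 3, or Day4 replicate 1, 2 or 3, 0 genes were lower, and without Day4 replicate 4, 2 were. From Day4 to Day5, edgeR, DESeq2 and limma-voom each called 0 genes, and 199 of the 13549 had an unadjusted p under 0.05 in edgeR. That is below the share of 0.05 that unchanged genes would reach by chance. The edgeR p-values of this step therefore ran high, and its 0 calls do not show that no gene changed. Replicates 1 to 3 alone gave 138 genes higher and 265 lower on Day4 than on Day3, and 8 higher and 1 lower on Day5 than on Day4.

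The later part of the time course differed from its start: 2252 genes were higher and 2266 lower on Day5 than on Day1, and 813 of these were at least 2-fold higher and 220 at least 2-fold lower. Replicates 1 to 3 alone gave 3447 genes higher and 3403 lower, 1184 and 387 of them at least 2-fold, and the filter of 5 CPM in 4 libraries gave 270 and 134 of at least 2-fold. Among the 2321 genes that were higher on Day1 than on Day0, 290 rose further by Day5 and 1207 had no call between Day1 and Day5. Another 824 were lower on Day5 than on Day1, of which 176 were still above Day0, 587 had no call against Day0 and 61 were below Day0. Among the 1963 genes that were lower on Day1, 184 fell further, 1308 had no call between Day1 and Day5, and 471 rose again, 348 of these with no call against Day0 and 53 above it. Other genes had no call on Day1 and changed later: 1163 genes were higher and 908 lower on Day5 than on both Day0 and Day1. On every treated day 1171 genes were higher than Day0 and 954 were lower.

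Because the comparisons of Day1 with Day0 and of Day5 with Day1 share the Day1 libraries, chance values there favour a rise followed by a fall or a fall followed by a rise. When the Day1 libraries were split so that the comparisons shared none, between 454 and 517 genes rose and then fell, and between 218 and 237 fell and then rose, with 2 Day1 libraries in each comparison. Between 94 and 350 rose and rose further, and between 21 and 226 fell and fell further. With Day1 replicate 4 among the libraries set against Day0, 340, 343 or 350 rose further and 207, 210 or 226 fell further. With it among those set against Day5, the counts were 94, 111 or 139 and 21, 43 or 73. Every split left Day1 replicate 4 on a single side, so these ranges also carry its difference from the other replicates. From replicates 1 to 3 alone, unsplit, 1344 genes rose and then fell, 746 of them with no call against Day0 on Day5 and 307 below it. Another 976 fell and then rose, 559 with no call against Day0 and 264 above it, while 542 rose further and 482 fell further.

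Genes changed by Day1 tended to be changed in the same direction on Day5. Against Day0, 1401 genes were higher on both days and 1298 were lower on both, while 114 had opposite directions. Independent lists of these sizes would share 549 higher and 424 lower genes. Unchanged groups compared with a shared Day0 group, all simulated around the Day0 means, shared 0 genes in each of 20 simulations. The value for independent lists leaves out the shared Day0 libraries. The simulation leaves out the real changes, so few genes can be called in it and its 0 is a weak reference. With Day0 split into sets of 2 libraries, a set for each comparison, between 894 and 1055 genes were higher on both days and between 780 and 937 lower on both, against 305 to 339 and 237 to 252 for independent lists.

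None of the 29 groups tested, which were chromosomes and classes of genomic span, was called against Day0 on any day by limma's camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 290 tests. On chromosome 13, 131 of 405 tested genes were higher and 76 lower on Day5 (median log2 fold change 0.1, adjusted p = 1). Of the 244 genes that span 250 kb or more, 80 were higher and 46 lower on Day5 (median log2 fold change 0.14, adjusted p = 1). From Day3 to Day4, genes of 1 to 10 kb were lower as a group (median log2 fold change -0.06, adjusted p = 0.000795), and those of 50 to 100 kb (0.05, adjusted p = 0.0144), 100 to 250 kb (0.07, adjusted p = 0.000335) and 250 kb or more (0.06, adjusted p = 0.0406) were higher. Each of these 4 calls had an adjusted p = 1 with an estimated correlation, and each was lost without Day3 replicate 3, where the medians were -0.027, 0.019, 0.017 and 0.012 (camera adjusted p = 0.998 for each). The class of 50 to 100 kb was also lost without Day4 replicate 3 (median 0.036, adjusted p = 0.233) or 4 (0.047, adjusted p = 0.0717), and the class of 250 kb or more without Day3 replicate 1 (0.054, adjusted p = 0.086) or Day4 replicate 3 (0.06, adjusted p = 0.0971) or 4 (0.033, adjusted p = 0.999). With no filter on low counts, the classes of 1 to 10 kb, 50 to 100 kb and 250 kb or more had medians of -0.017, 0.049 and 0.051 and did not pass (camera adjusted p = 0.21, 0.255 and 0.219). For the 723 genes under 1 kb, the level per library relative to other genes was -3.46 ± 0.032 log2 units (SD, n = 4) on Day0 and -3.71 ± 0.054 on Day5, and each Day0 library lay above every library of Day2 to Day5. The exact two-sided permutation p was 0.0286 on each of these 4 days, the smallest that 4 libraries against 4 allow, and the adjusted p was 0.107, so this test leaves the difference open.

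Of 15 genes of the mitochondrial genome at 50 CPM or more, 2 were lower than Day0 on Day2, 3 on Day3 and 4 on Day5 by edgeR's test, and 0 on Day1 and Day4. Of all 13549 genes tested, 1896 were lower on Day2, 2721 on Day3 and 2926 on Day5. The shares of the 15 genes were near these, and below those of all genes on Day1 and Day4. The median log2 fold changes of the 15 genes from Day1 to Day5 were -0.21, -0.4, -0.31, -0.11 and -0.39. Per library their level relative to other genes differed from Day0 by -0.52 log2 units on Day5 (exact two-sided permutation p = 0.0571, adjusted p = 0.161), and no day passed. The smallest permutation p that 4 libraries against 4 allow is 0.0286, and the adjustment also took in other gene groups. No day could pass by the mitochondrial values alone, so this test leaves the difference open. The group of all 21 tested mitochondrial genes was not called against Day0 on any day, with a camera adjusted p = 0.747 on Day5. Over the same 21 genes the median log2 fold change from Day4 to Day5 was -0.27 (camera adjusted p = 0.000335), and -0.511 in replicates 1 to 3 (camera adjusted p = 8.05e-10). With an estimated correlation the adjusted p was 1 for all libraries. That call was also lost without Day4 replicate 1 (median -0.192, adjusted p = 0.108), without Day4 replicate 2 (-0.14, adjusted p = 0.356) and without Day5 replicate 2 (-0.163, adjusted p = 0.895). The estimated correlation was not run on replicates 1 to 3 alone. Relative to other genes, the 15 genes went from 7.068 to 6.623, 7.141 to 6.198 and 6.759 to 6.549 log2 units there. In replicate 4 they rose from 6.431 on Day4 to 6.978 on Day5.

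Genes that rose strongly lay next to one another more often than in shuffled gene orders. On Day1, 64 pairs of adjacent, non-overlapping tested genes were both at least 2-fold higher, against a mean of 20.2 and a maximum of 37 in 1000 shuffles within chromosomes (one-sided permutation p = 0.001, the smallest these can give). On Day5 there were 208 such pairs, against a mean of 107 and a maximum of 145 (permutation p = 0.001). For genes at least 2-fold lower the pairs numbered 11 against 7.1 on Day1 (permutation p = 0.103) and 22 against 13.6 on Day5 (permutation p = 0.023). With replicates 1 to 3 alone, rising pairs numbered 88 on Day1 and 251 on Day5, both with a permutation p = 0.001, and falling pairs 23 (permutation p = 0.014) and 34 (permutation p = 0.105). The longest run on both days held 6 tested genes on both strands of chromosome 8 from 62723788 to 62993127. The gene there from 62984552 to 62987182 rose from 0.0171 CPM on Day0 (2 reads) to 9.53 CPM on Day1 and 28.1 CPM on Day5. The gene from 62723788 to 62745868 rose from 0.843 CPM to 4.39 and 8.38 CPM. Other members stayed low: those from 62946732 to 62948720 and from 62991763 to 62993127 had 0 reads on Day0. On Day5 they were at 0.8 and 0.42 CPM. On Day5, runs of 5 rising genes were found on chromosome 1 from 89464860 to 89560719 and on chromosome 18 from 30375798 to 30418372, the latter all on the plus strand with log2 fold changes of 1.51 to 2.51. A further 4 rising genes lay on chromosome 18 from 30474947 to 30512411. The longest falling run, of 4 genes on Day1, lay on chromosome 17 from 43797721 to 43821536, with log2 fold changes between -1.93 and -1.57. Neighbouring genes can be near-identical copies, between which the authors' counting may have divided reads, so the levels of single genes within runs are uncertain.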

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

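In this part the tests of a batch, of each replicate number against the others and of the mean difference over the 6 days were chosen after the results had been seen. So were those of the distance from Day0 to Day5, with and without thinning. The test of depth on the genes called and the test of label swaps by the best-matching day were chosen before.

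Within the 4 libraries of a day, 1 library lay far from the other three in 14 of 76 sets of values examined, where simulated normal values give 5.1% of sets, and that library was replicate 4 in 13 of the 14. The sets are not independent of each other. On the first principal component replicate 4 was at -45.2 on Day0 (the others from -66.4 to -63.2), at -2.75 on Day1 (-34.9 to -32.9) and at 18.3 on Day5 (39.7 to 42.7). On the second component it was at 37.6 on Day0, 5.87 on Day1, 9.42 on Day2, 22 on Day4 and 20.2 on Day5, each above the other libraries of its day. The Day5 library of replicate 4 had 15100 genes with a count, against 16100 to 16200 in the others. ENSRNOG00000049882 was at 26.5 CPM in replicate 4 on Day4 against 89.9 to 93 CPM, and ENSRNOG00000029342 at 17.5 CPM against 7.09 to 7.39 CPM. ENSRNOG00000002487 was at 4.7 CPM in replicate 4 on Day1 against 1.51 to 2 CPM, and ENSRNOG00000003587 at 12 CPM on Day0 against 41.7 to 42.3 CPM. The remaining value was the Day2 library of replicate 1, where mitochondrial genes at 50 CPM or more lay 7.13 log2 units above the mean of other genes, against 6.48 to 6.54 in the other Day2 libraries.

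Replicate 4 stood apart on all 6 days, and 4925 genes separated it from replicates 1 to 3, while replicates 1, 2 and 3, each set against the other members of replicates 1 to 3 with replicate 4 left out, gave 0 genes each in edgeR, and replicate 4 against 2 of them gave 3901 to 4155. A difference in depth is argued against: with every library thinned to the smallest total, 94.6% as many genes were called. Of the replicate 4 libraries, 4 of 6 matched their own day best, against 6 of 6 for each other replicate, so the bound set beforehand for swapped labels was met; but the Day3 library matched Day4 (r = 0.48 against 0.454 for its own day) and the Day4 library matched Day5 (0.628 against 0.608), so none had traded places with another, and swaps of single days stay open. Swaps between days leave the mean over the 6 days as it is, and the SD over genes of that mean difference was 0.269 log2 units for replicate 4 against at most 0.12 for the others, which argues against swaps as the cause of the mean difference. A separate culture or library batch may account for the 4925 genes, and because the labels give no batch it cannot be told apart from a difference in the cells themselves. Of such differences only copy number was examined, in windows of neighbouring genes further below, and it stayed open.

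Replicate 4 also moved less between Day0 and Day5. On genes and an axis from replicates 1 to 3, whose mean moves by 1 there, it moved by 0.57; on those from each 2 of replicates 1 to 3, the one left out moved by 0.89 to 0.95 and replicate 4 by 0.55 or 0.56. On the axis from replicates 1 to 3, its libraries from Day0 to Day5 stood at 0.18, 0.6, 0.69, 0.79, 0.84 and 0.75. In position it was thus not behind on Day1 or Day2: replicates 1 to 3, each on the axis from the other members, stood at 0.4 to 0.42 and 0.56 to 0.59. They had started lower, at 0.02 to 0.07 on Day0. These positions therefore do not show that replicate 4 had moved further from its own Day0 by then. The distance of replicate 4 from Day0 to Day5 is further below the others than their own range, which argues against their chance spread as the cause. Thinning all libraries to the smallest total left the distance at 0.57, which argues against depth. Other causes were not tested.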

How the results depend on the processing

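The alternatives with replicates 1 to 3 only and with replicate 4 as a batch term were chosen after seeing the data, and the others before. Of the counts of genes called, 373 under an alternative lay within 1.5 times the count reported, 52 lay outside, 5 rose from 0 and 7 fell to 0. The 373 include counts of 0 that stayed 0. A count has no direction to reverse, and no fold change of a named gene or group median that was called changed sign. Every count of genes higher or lower than Day0 and the count of any difference stayed within 1.5 times under every alternative run. The counts shared by Day1 and Day5 (1401 higher, 1298 lower) did so too, apart from single splits of Day0 into sets of 2 libraries, which gave as few as 894 and 780. The other exceptions were in steps between successive days and, with replicates 1 to 3 only, in Day5 against Day1 (3447 higher, 3403 lower). For Day2 against Day1 (302 higher and 306 lower), DESeq2 gave 485 and 536, the 2 groups alone 7 and 1, replicates 1 to 3 only 1689 and 1515, and the batch term 766 and 704. For Day3 against Day2 (256 and 234), these gave 458 and 378, 144 and 91, 1430 and 1246, and 718 and 559. For Day4 against Day3 (0 and 1), DESeq2 gave 3 lower, limma-voom and the 2 groups alone 0 lower, replicates 1 to 3 only 138 and 265, and the batch term 7 and 5. For Day5 against Day4 (0 and 0), replicates 1 to 3 only gave 8 and 1. The cause was not tested, except that the batch term removes the mean difference of replicate 4 from the spread.

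Leaving out a library moved Day2 against Day1 to between 89 (without Day1 replicate 1) and 1334 (without Day1 replicate 4) genes higher and between 79 (without Day1 replicate 2) and 1143 (without Day1 replicate 4) lower. Day3 against Day2 ranged from 54 (without Day2 replicate 2) to 475 (without Day2 replicate 4) higher and from 62 to 456 lower, with the same libraries left out. For Day4 against Day3, 0 genes were lower without Day3 replicate 1 or 3 or Day4 replicate 1, 2 or 3, and 2 without Day4 replicate 4. For Day2 against Day1 and Day3 against Day2, the values for the other libraries stand with the results.

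The replicate number as a block gave 674 higher and 630 lower for Day2 against Day1, 609 and 449 for Day3 against Day2, and 5 and 4 for Day4 against Day3, and it moved no other count of all genes higher or lower by over 1.5 times. The numbers do not pair the libraries by the rule set: deviations from the day's mean correlated at 0.437 on average between replicate 4 libraries (lowest 0.219), but at 0.121, 0.0851 and 0.11 for numbers 1, 2 and 3, with lowest values of 0.0321, -0.129 and -0.0885. All 6 libraries of number 4 matched their own number best, against 4, 0 and 4 of 6 for numbers 1 to 3, which is a hint from the data and not from the design.

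Counts of changes of at least 2-fold fell under the stricter filter, which tests fewer genes of low count. Higher genes were 336 on Day1 (538 reported), 339 on Day2 (641), 491 on Day3 (1056), 545 on Day4 (1201) and 564 on Day5 (1232) against Day0, and 270 for Day5 against Day1 (813). Lower genes were 180 (313), 91 (210), 137 (289), 215 (399), 253 (444) and 134 (220). In the simulation of Day1 against Day0, 52.2% of changes of 1.5-fold were recovered. For gene groups, fry, which asks whether a group changed at all and not whether it differs from other genes, called none of the 5 groups camera called: the span classes from Day3 to Day4 had an adjusted p of 0.753 or 0.808, and the mitochondrial genes from Day4 to Day5 had 0.808. With replicates 1 to 3 only, genes of 250 kb or more were higher from Day4 to Day5 (median 0.059, camera adjusted p = 0.0157), and with the stricter filter genes under 1 kb were lower from Day3 to Day4 (median -0.127, camera adjusted p = 0.000392). With an estimated correlation, run on all libraries with the usual filter only, the adjusted p was 1 for both, and without Day3 replicate 3, with that filter, the median of genes under 1 kb was 0.019. The alternatives for the gene lists of named genes were not run, since the files hold no names, nor were those for normalized values, since the files hold counts.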

Other observations

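The tests of neighbouring windows and the order of genes by level in this part were chosen after the results had been seen, and the splits of the libraries before.

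Abundant genes had more rises than falls on Day1. With genes ordered by the mean log2 level of Day0 and Day1 together, on which a rise and a fall of the same size weigh alike, 39 of the top 100 were higher and 7 lower on Day1 than on Day0, 13 and 0 of them at least 2-fold, in edgeR. Of the next 900 genes, 311 were higher and 106 lower, of the next 4000, 911 and 630, and of the 8549 genes at the low end, 1060 were higher and 1220 lower. On Day5, ordered in the same way with Day0, the top 100 had 29 higher and 16 lower, the next 900 had 244 and 192, the next 4000 had 857 and 1094, and the 8549 low genes had 2072 higher and 1624 lower. The difference between these classes was not tested, and the counts are relative to TMM scaling.

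The genes at least 2-fold higher on Day1 held their largest share of the counts on that day: the 538 genes held 3.1% ± 0.213 (SD, n = 4) on Day0, 7.8% ± 0.214 on Day1 and 6.13% ± 0.201 on Day5. The 1232 genes at least 2-fold higher on Day5 held 2.36% ± 0.262 on Day0, 4.82% ± 0.621 on Day1 and 6.82% ± 0.64 on Day5. The 313 genes at least 2-fold lower on Day1 went from 1.67% ± 0.158 on Day0 to 0.614% ± 0.0318 on Day1 and 0.774% ± 0.0114 on Day5, and the 444 at least 2-fold lower on Day5 from 2.9% ± 0.36 to 1.64% ± 0.211 and 1.11% ± 0.036. These genes were chosen for their change in the same libraries.

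In windows of 40 neighbouring genes, replicate 4 differed from the other three replicates in the same direction in adjacent windows. The correlation of adjacent window medians was 0.466 over 254 windows, above the highest of 1000 shuffles of the genes (0.22), which argues against a chance order. Against the other members of replicates 1 to 3, replicate 1 gave 0.458 (SD of window medians 0.0345), replicate 2 gave -0.0151 (0.00935) and replicate 3 gave 0.465 (0.0341), where the windows of replicates 1 and 3 mirror each other (r = -0.932) and so count as 1 such case, with a narrower spread than in replicate 4 (0.064). A technical trend shared with other libraries may account for it: against the windows of replicate 1, taken on alternate days so that no library enters both, the correlation was -0.477 for one assignment of the days and -0.0719 for the other, which leaves it open. A difference in copy number in the cells of replicate 4 is open too, since its windows on Day0, Day2 and Day4 correlated at 0.826 with those on Day1, Day3 and Day5 (0.0985, -0.831 and 0.76 for replicates 1, 2 and 3), as they would under a lasting batch difference.

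Other splits of the libraries into groups of 4 were tested in fits of the 8 libraries of each comparison alone, so the counts differ from those with all libraries. A chance arrangement of the libraries is argued against for each treated day against Day0. In each case 1 of 35 splits, the real one, gave as many calls, and the highest other split gave 0. A share of 1 in 35 is the smallest these splits can give and is not adjusted over the comparisons. Every other split mixes days within a side, which widens the spread there. The real splits gave 3378 genes on Day1, 3638 on Day2, 5161 on Day3, 6310 on Day4 and 5707 on Day5. A chance arrangement is argued against also for Day3 against Day2 (235 genes, highest other 2) and Day5 against Day1 (3116, highest other 208). The 208 came from a split that exchanged Day1 replicate 4 and Day5 replicate 4 between the sides. For any difference among the days, 1 of 100 splits of the 24 libraries, the real one, gave as many (7552, highest other 65). A chance arrangement stayed open for Day2 against Day1, where 2 of 35 splits gave at least the 8 genes of the real one. The other split exchanged Day1 replicate 4 with Day2 replicate 1 and gave 743 genes, many times the real count, which points to a structure of the samples; in a fit of replicates 1 to 3 of all 6 days, which is not of the same form, the comparison gave 1689 higher and 1515 lower. For Day4 against Day3 and Day5 against Day4 the real count in these fits was 0, which all 35 splits must reach, so nothing is decided there. The highest other count was 62 for Day4 against Day3, from the split that exchanged Day3 replicate 2 with Day4 replicate 4, which again points to a structure of the samples, and 0 for Day5 against Day4.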
